A study of Danio rerio with 12 samples.

How the data were processed

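Gene expression was measured by low-input RNA sequencing in 12 libraries of zebrafish trunk neural crest, each made from 20 sorted cells. Per the labels' protocols, cDNA was amplified with SMART-Seq v4 chemistry for small samples and libraries were prepared by Nextera tagmentation. fastp 1.0, Salmon and the genome build GRCz11 are named in the submitters' processing notes, with no role or order. The deposited table holds a normalised signal per gene that the authors made from read counts, as its name says. The method of normalisation, the annotation and any filter are not given in the sources used here. Values within a fixed window around 1 had a median of 0.958 to 1.05 per library, which the window itself places near 1. Only 12.7% to 44.7% of low values per library were whole multiples of 1 step within a fixed tolerance, on which this share depends. Whole reads were therefore not recovered, and no model for counts was run. The depth is known only as far as the sums of the deposited values show it, 10735983 to 24227327 per library, and amplified reads without molecular identifiers are not independent molecules.

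The table has 25878 gene identifiers, of which 23604 matched a symbol in the gene name table used, 2274 did not and 783 were at 0 in every library. A symbol is shared by 3440 identifiers, since paralogs often carry the same human-style name, so reads of near-identical copies may be split between them. The number of columns left out was 0. The highest Pearson correlation of any 2 libraries was 0.662, so none was a copy of another. Groups were taken from the library names in the labels.

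Migratory libraries were compared with premigratory libraries in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with a trend on log2(value + 1), over genes with a value of 10 or more in at least 4 libraries. Calls have a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Camera with an inter-gene correlation of 0.01 compared each of 36 gene lists, with 3 or more tested members, with the other genes, and was repeated with an estimated correlation, with which no list was called. After the data were seen, the median of each list was also placed among 10000 random lists matched on mean value. Of 1182 symbols in these lists 1121 were matched, 266 of them only after removing the paralog letter. The pattern for Hox genes had asked for a paralog letter, which was made optional because most symbols carry none, and case was ignored there and for ribosomal proteins. Single measures per library were compared by exact two-sided permutation of all arrangements of 4 among 12 libraries, with adjustment over 15 measures. The p-values measure the spread between these libraries.

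The test, lists, gene naming rule and most alternatives were fixed before the data were examined. Named genes are the 12 largest rises and 12 largest falls among called genes with a mean of 50 or more and no overlap between groups (8 fell), up to 4 members of each list with the smallest p, and a fixed set of crest, damage response and nuclear envelope genes. Genes without a symbol were counted only, and some results are not reported here.

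Both groups are numbered from 1, and the labels also call the number a batch, so the number was taken to pair libraries 1 to 4. Deviations from the group means correlated at 0.155, 0.0118, 0.0424 and 0.0342 for the same-numbered pairs 1 to 4. Their mean was 0.0609, against -0.0197 for different numbers, where the highest value was 0.0287. All same-numbered values but 0.0118 lay above that highest value, so same-numbered libraries were slightly more alike. The main test did not use the pairing. Results with the number as a fixed and as a random block are given below. Batches 5 to 8 hold migratory libraries only and say nothing on the group difference within a batch.

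The scripts were tested on simulated data for this comparison, with 12122 genes of which 200 were changed. The median fitted size was 1.79, 3.32 and 7.13 for simulated log2 changes of 2, 4 and 8, and 0%, 11.9% and 54.5% of these genes were recovered, with 3 false calls. Alternatives covered the pseudocount, the filter, the scaling (trimmed mean of M values, median of ratios, same total and quantile normalisation, all written for the deposited values), weights, a rank test, the replicate block, covariates and leaving out libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.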

Results

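Trunk neural crest cells were taken from zebrafish embryos in which a sox10-driven histone fused to the photoconvertible protein Dendra2 marks crest nuclei. The neural crest is an embryonic cell population that leaves the dorsal neural tube and forms, among others, pigment cells, peripheral neurons and glia. Cells converted by light were sorted, and RNA of 20 cells per library was sequenced. The 12 libraries fall into 4 of premigratory crest at 16 hours after fertilisation and 8 of migratory crest at 24 hours, the latter taken beside somites 10 to 15. The deposited normalised values summed to 10735983 to 21711424 in premigratory and 17765775 to 24227327 in migratory libraries. Leader and follower cells are named in the sampling protocol, but the labels do not say which migratory library holds which, so migratory libraries were kept as 1 group. Replicates are labelled as biological; the number of embryos behind each library was not used here.

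The study compared crest cells before and after they had moved through narrow spaces between tissues, with protection from DNA damage as its stated theme. Migratory libraries had higher values of 1508 genes and lower values of 16, of 12122 tested. The largest rises were in genes nearly absent from premigratory libraries. HOXD9, a posterior axial patterning regulator, had a mean value of 6888 ± 5217 (SD, n = 8) in migratory and 1.75 ± 2.38 (SD, n = 4) in premigratory libraries, a log2 fold change of 11.14 (SE 1.34, adjusted p = 0.000398). GAPDH, a glycolytic enzyme, stood at 15442 ± 16955 against 3.48 ± 3.79 (its relation to muscle markers is given below), and WNT11, a signal of the planar polarity pathway, at 5201 ± 6389 against 0.477 ± 0.953.

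The other genes with the largest rises were RIMOC1, DCTN5, CITED1, UFC1, si:ch211-210c8.7, ECHS1, emc9, prdx6 and rnaset2, with log2 fold changes of 10.37 to 10.86. Of these, DCTN5 is a subunit of dynactin, UFC1 an enzyme of the UFM1 conjugation pathway, ECHS1 an enzyme of mitochondrial fatty acid oxidation and prdx6 a peroxiredoxin. All migratory libraries lay above all premigratory libraries for 535 of the 1508 higher genes and below them for 8 of the 16 lower genes. Of all 12122 tested genes 586 were separated upwards and 17 downwards, where chance gives 0.202% per direction, so separation downwards was no more frequent than by chance. Of the higher genes, 857 (56.8%) were under 10 in every premigratory library. The median log2 fold change of all tested genes was 2.67, so a gene with a log2 fold change of 2.67 changed as much as the typical tested gene. This median depends on which genes are tested, with 0.94 under no filter and 0.21 over genes at 10 or more in every library. A gene seen only in migratory libraries passes the filter with 4 of 8 libraries at 10 or more. A gene seen only in premigratory libraries needs all 4.

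The 8 lower genes with separated groups were DDX51, si:ch211-212k18.5, si:ch211-154a22.8, pprc1, ZBTB16, olfcr1, si:dkeyp-4c4.1 and MYEF2. ZBTB16, a zinc finger transcription factor, fell from 31055 ± 25467 (SD, n = 4) to 1304 ± 1570 (SD, n = 8), a log2 fold change of -6.00 (SE 1.55, adjusted p = 0.0207). DDX51, an RNA helicase of ribosome assembly, fell from 2242 ± 1391 to 69.6 ± 136, and pprc1, a coactivator of mitochondrial gene expression, from 4371 ± 3318 to 175 ± 192. Among the other lower genes were twist1b and DLX5, transcription factors of the crest, and SERPINH1, a collagen chaperone.

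The test was limma on log2(value + 1) with Benjamini-Hochberg adjustment, and an unadjusted p under 0.05 was reached by 3850 higher and 80 lower genes. With the shared number of the libraries as a replicate block no gene was called in either direction (0 higher, 0 lower), a fit with few residual degrees of freedom, while the number as a random block (correlation 0.0175) gave 1543 higher and 17 lower. Quantile normalisation, which sets the median shift to 0, gave 139 higher and 53 lower genes (72.4% higher, against 98.95% of the calls above).

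**Figure D1:**
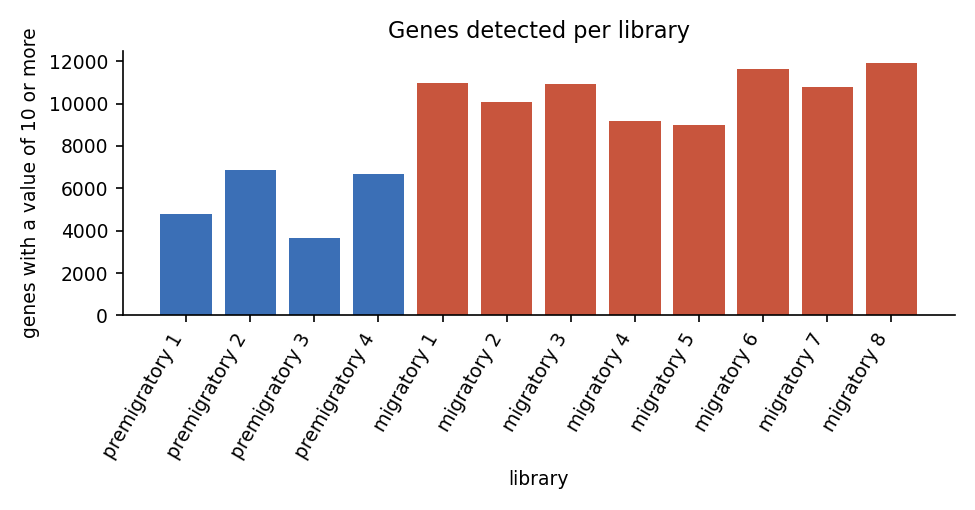
Number of genes with a value of 10 or more (vertical axis) in each of the 12 libraries (horizontal axis), with premigratory libraries in blue and migratory libraries in red. Premigratory libraries hold 3650 to 6879 such genes and migratory libraries 9007 to 11896.

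Premigratory libraries held fewer genes with clear signal. The number of genes at 10 or more was 5489 ± 1547 (SD, n = 4) in premigratory and 10559 ± 1058 (SD, n = 8) in migratory libraries (exact permutation test, two-sided, p = 0.00202, the smallest this test can give, and adjusted p = 0.0303 over 15 measures). The number of genes above 0 was 13100 ± 5083 against 16812 ± 2840 (exact permutation p = 0.125, adjusted p = 0.376). Mitochondrially encoded genes took 2.85% ± 1.64 of the total in premigratory and 2.41% ± 0.691 in migratory libraries (exact permutation p = 0.519), and ribosomal protein genes 6.02% ± 2.08 and 5.10% ± 3.55 (exact permutation p = 0.689). The 10 most abundant genes took 8.49% ± 4.17 and 12.22% ± 8.68 (exact permutation p = 0.491), and the 100 most abundant 26.1% ± 5.05 and 28.7% ± 7.68 (exact permutation p = 0.606). Without premigratory replicate 4 the difference in genes above 0 was 6000 (exact permutation p = 0.0182).

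General crest genes were present at both stages. SOX10, the crest regulator whose promoter drives the reporter, was at 9057 ± 5320 (SD, n = 4) in premigratory and 10547 ± 6764 (SD, n = 8) in migratory libraries, a log2 fold change of -0.02 (SE 0.71, adjusted p = 0.987). The crest transcript crestin was at 2544 ± 2038 and 8009 ± 5452 (adjusted p = 0.238) and TFAP2A at 1708 ± 1984 and 7163 ± 4934 (adjusted p = 0.0906). Of the 25 tested genes of the shared crest list 3 rose, namely zeb2a, tspan36 and erbb3b (3 when adjusted over the list alone), and the list was not called against other genes (camera, adjusted p = 0.121), but was called as rising less without premigratory replicate 1 (adjusted p = 0.0170). Of 24 early crest genes 2 rose (FOXD3 and PAX3) and 2 fell (twist1b and DLX5), with 4 and 2 when adjusted over the list alone (camera, adjusted p = 0.0563, and 0.0448 with the replicate block). FOXD3 went from 1368 ± 1584 to 6759 ± 3343, a log2 fold change of 5.65 (SE 1.65, adjusted p = 0.0357), and snai1b was at 332 ± 651 and 138 ± 141 (adjusted p = 0.640). The lowest values of crestin were 5.97 in premigratory replicate 1, where epidermis markers were highest, and 135 in migratory replicate 5, where blood markers were highest.

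**Figure D2:**
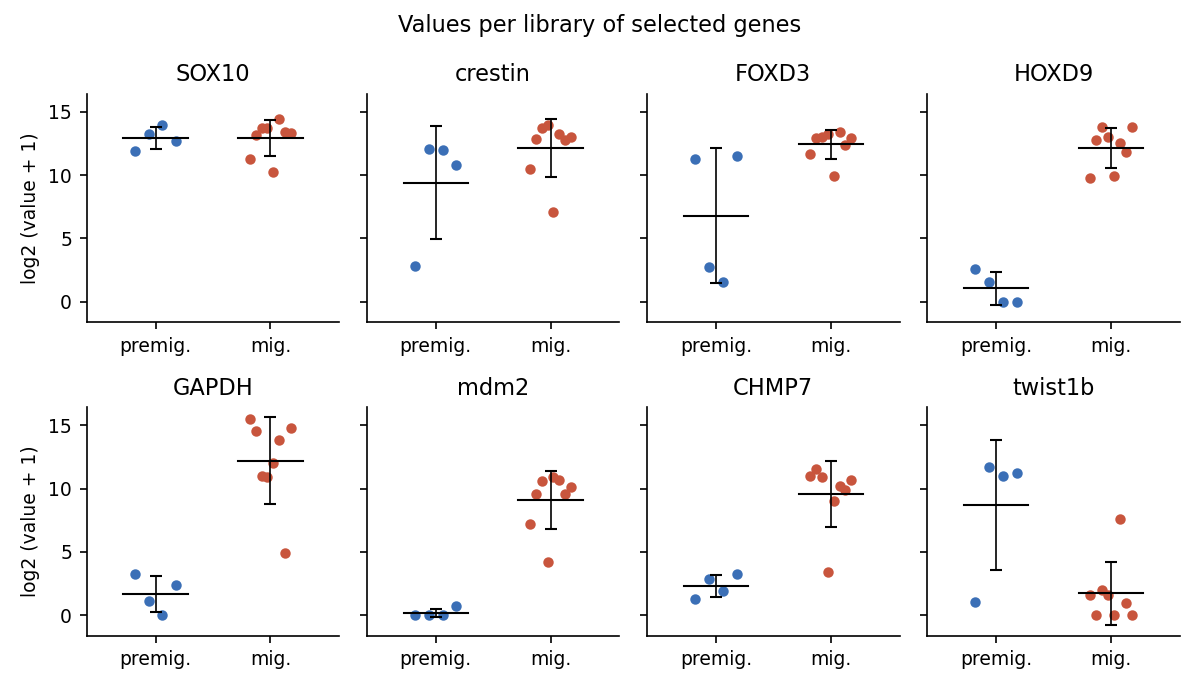
Values of 8 genes, as log2 of the value plus 1 (vertical axis), in the 4 premigratory (blue) and 8 migratory (red) libraries, with 1 point per library, the mean as a horizontal line and the SD as an error bar. SOX10 is present in all 12 libraries, whereas HOXD9, GAPDH and mdm2 lie under 10 in all premigratory libraries.

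Hox genes and pigment genes rose beyond the general shift. Of 32 tested Hox genes, which set position along the body axis, 11 rose and 0 fell (24 rose when adjusted over the list alone), with a median log2 fold change of 5.73 (camera, adjusted p = 3.06e-05, but adjusted p = 0.466 with an estimated correlation). Besides HOXD9 they included HOXA11 (log2 fold change 9.39, SE 1.39), HOXD10 (8.81, SE 1.84) and HOXB7 (7.07, SE 1.56). The mean log2 value of the tested Hox genes was 0.78 to 3.08 in premigratory libraries, 2.73 in migratory replicate 5, the richest in blood markers, and 7.34 to 9.98 in the other 7 migratory libraries. Of 29 pigment lineage genes 9 rose and 0 fell (13 when adjusted over the list alone), with a median of 5.51 (camera, adjusted p = 0.00193, but adjusted p = 0.596 with an estimated correlation). GPR143, a melanosome receptor, rose from 2.62 ± 2.47 to 7372 ± 7855, and MITF, the melanocyte regulator, in 1 of its 2 identifiers from 4.39 ± 2.72 to 5149 ± 5771 (log2 fold change 8.26, SE 1.91, adjusted p = 0.0126). ALX4, trpm1b and BACE2 also rose. Of 9 neuronal and glial genes 2 rose, FABP7 and erbb3b (3 when adjusted over the list alone; camera, adjusted p = 0.950).

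Glycolytic, antioxidant and ESCRT genes formed another set of rising lists. Of 23 glycolysis genes 11 rose and 0 fell (13 when adjusted over the list alone), among them GAPDH, GAPDHS, TPI1 and PKM, with a median of 6.12 (camera, adjusted p = 0.00115, but adjusted p = 0.466 with an estimated correlation). In a comparison chosen after the data were seen, the rank correlation with the mean of muscle markers over the 8 migratory libraries was 0.952 for 1 identifier of ALDOA, which did not pass as higher (exact p = 0.00114, adjusted p = 0.024 over the list), 0.857 for ENO1 (exact p = 0.0107, adjusted p = 0.112), which rose, 0.786 for GAPDH (exact p = 0.0279, adjusted p = 0.195) and -0.357 for 1 identifier of GPI, which rose, with a median of 0.262 over the 11 genes that rose. For the mean of the glycolysis list it was 0.643 (exact p = 0.0962). The same rank correlation was 0.571 for the ESCRT list (exact p = 0.151) and 0.429 for damage-induced genes (exact p = 0.299). It was 0.357 for Hox (exact p = 0.389), -0.143 for antioxidant (exact p = 0.752) and -0.452 for pigment genes (exact p = 0.267). Of 32 antioxidant genes 8 rose (10 when adjusted over the list alone), including prdx6, SOD1, TXNRD3 and prdx1, with a median of 3.19 (camera, adjusted p = 0.0250, but adjusted p = 0.466 with an estimated correlation and 0.0948 with the replicate block and 0.178 without premigratory replicate 2). Of 22 genes of the ESCRT machinery, which reseals membranes including the nuclear envelope, 7 rose (13 when adjusted over the list alone), with a median of 5.08 (camera, adjusted p = 0.00864, but adjusted p = 0.5 with an estimated correlation and 0.101 without premigratory replicate 2). CHMP7, the ESCRT adaptor of the nuclear envelope, rose from 4.63 ± 3.15 (SD, n = 4) to 1401 ± 949 (SD, n = 8), a log2 fold change of 7.28 (SE 1.66, adjusted p = 0.0121). tsg101a was listed at 0 in all premigratory libraries and at 1620 ± 1166 in migratory ones, while chmp4bb and CHMP2A rose by 6.46 and 6.14 on the log2 scale.

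Genes of the DNA damage response were measured against the same shift. Of 21 damage-induced genes 4 rose, namely mdm2, SESN1, DDB2 and EI24 (6 when adjusted over the list alone), with a median of 4.36 (camera, adjusted p = 0.0317, but adjusted p = 0.466 with an estimated correlation and 0.202 with the replicate block). The call of this list was also lost without premigratory replicate 2 or 3 (adjusted p = 0.110 and 0.118) or migratory replicate 1, 5 or 8 (adjusted p = 0.0605, 0.0774 and 0.0659). The ubiquitin ligase mdm2 went from 0.151 ± 0.303 to 998 ± 705, a log2 fold change of 8.95 (SE 1.59, adjusted p = 0.00227), whereas cdkn1a was at 120 ± 241 and 154 ± 272 (adjusted p = 0.607). The repair lists did not move apart from other genes. In homologous recombination 2 of 19 rose, RAD54L and rad51d (5 when adjusted over the list alone; camera, adjusted p = 0.253), in end joining 2 of 17, nhej1 and TDP2 (4; adjusted p = 0.950), and in damage signalling 2 of 21, rad9a and HUS1 (0; adjusted p = 0.811). In excision repair 3 of 38 rose, ERCC2, DDB2 and TDG (3; adjusted p = 0.667), and in crosslink repair FAAP24 alone of 15 (1; adjusted p = 0.950). XRCC5 was at 665 ± 1296 and 1648 ± 1765 (adjusted p = 0.0670) and XRCC6 at 1312 ± 1515 and 1122 ± 968 (adjusted p = 0.441). For CHEK1, brca2 and ATM the adjusted p was 0.255, 0.447 and 0.222, and ATR lay below the filter on low values. The medians of end joining and excision repair lay above that of all genes while camera gave a downward sign for both.

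Few genes of nuclear structure passed the test, which sets them little apart, since 1508 of all 12122 tested genes rose. Of 18 genes of the nuclear lamina and its cytoskeletal links SUN1 alone rose (log2 fold change 5.25, SE 1.65, adjusted p = 0.0461; 0 when adjusted over the list alone; camera, adjusted p = 0.774). LMNB1 was at 1492 ± 1476 and 3231 ± 1673 (adjusted p = 0.160), LMNB2 at 4434 ± 2280 and 3398 ± 2725 (adjusted p = 0.667), LMNA at 5.49 ± 5.04 and 45.7 ± 109 (adjusted p = 0.739) and LBR at 3799 ± 3555 and 4679 ± 3322 (adjusted p = 0.746). In the heterochromatin list 4 of 41 rose, BMI1, RNF2, CBX8 and DNMT1 (3; adjusted p = 0.667), and in cohesin and condensin nsmce2 alone of 24 (0; adjusted p = 0.950). The adhesion list had 4 of 48 up, among them zeb2a, mmp17b and ctnna1, and twist1b down (4 and 1; adjusted p = 0.204), and actomyosin 5 of 50 up, among them ARPC5, ARPC3, ROCK2 and rhoac (0; adjusted p = 0.336). No gene passed in the mechanosensitive list of 18 (adjusted p = 0.155), where YAP1 was at 4950 ± 5268 and 1665 ± 1136 (adjusted p = 0.910), or in the Notch list of 22 (adjusted p = 0.214). Of 23 Wnt and polarity genes WNT11 rose (adjusted p = 0.950).

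Of the 5 lists of cell functions called as rising less than other genes, the ribosomal and heat shock lists also lay low among genes of like mean value. The 80 tested ribosomal protein genes had a median log2 fold change of -0.03 and none passed (camera, adjusted p = 3.08e-10, but adjusted p = 0.596 with an estimated correlation). Heat shock and unfolded protein response genes had a median of 0.53, with SERPINH1 down among 37 (camera, adjusted p = 0.00238, but adjusted p = 0.466 with an estimated correlation), and immediate early genes 1.27, with ier2b up among 34 (camera, adjusted p = 0.0250, but adjusted p = 0.596 with an estimated correlation and 0.182 with the replicate block). DNA replication had a median of 1.94, with ORC6, RRM2B, PRIM1 and CDC45 up among 49, and mitosis 2.15, with bub1ba up among 45 (camera, adjusted p = 0.0491 for both, but adjusted p = 0.803 and 0.805 with an estimated correlation). In a comparison chosen after the data were seen, lists were placed among 10000 random lists matched on mean value. The median lay at percentile 0 for ribosomal, 0.47 for heat shock, 24.4 for immediate early, 25.4 for replication and 30.2 for mitosis genes. The last 3 did not stand apart from genes of like abundance. Of the lists called as rising more, antioxidant genes lay at percentile 91.8, damage-induced genes at 94.7 and the others at 99.75 or more. The random lists draw genes separately, while members of a list can vary together. The estimated correlation was 0.81 for ribosomal and 0.11 for heat shock genes. Percentiles near either end therefore overstate how far a list stood apart. All 5 calls of these lists rising less were lost with quantile normalisation (adjusted p = 0.294 ribosomal, 0.483 heat shock, 0.918 mitosis, 0.950 replication and 0.976 immediate early). The sign turned for the last 2. Heat shock was also lost without premigratory replicate 1 (adjusted p = 0.154). Immediate early was lost without premigratory replicate 1 or 3 or migratory replicate 5 (adjusted p = 0.283, 0.158 and 0.133). Replication was lost without premigratory replicate 2, 3 or 4 or migratory replicate 1, 3 or 8 (adjusted p = 0.178, 0.270, 0.110, 0.408, 0.0743 and 0.0659). Mitosis was lost without premigratory replicate 2, 3 or 4 or migratory replicate 1, 2, 3 or 7 (adjusted p = 0.207, 0.150, 0.150, 0.408, 0.0681, 0.0732 and 0.131). The 13 mitochondrially encoded genes had a median of 0.58 (adjusted p = 0.253).

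**Figure D3:**
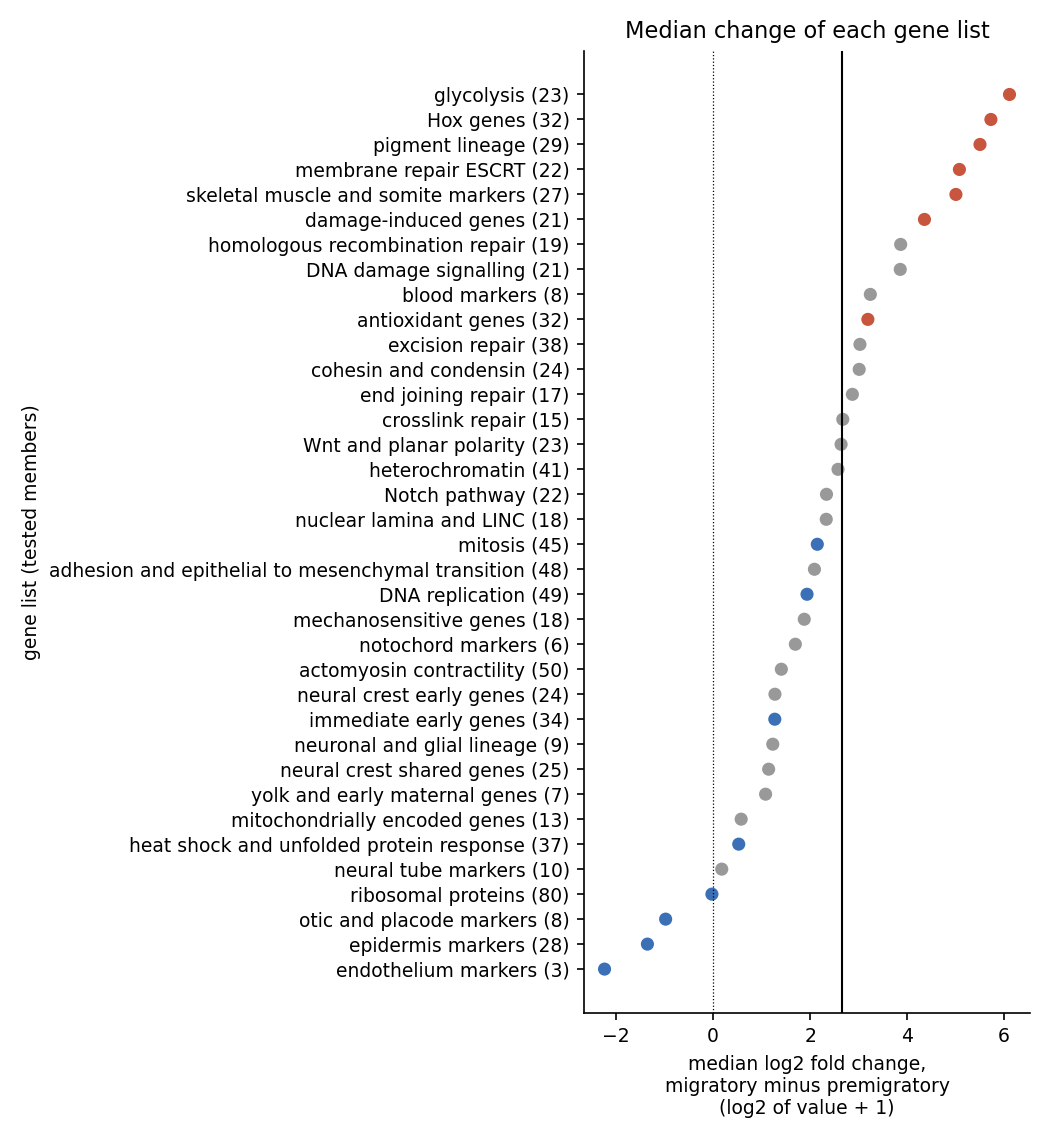
Median log2 fold change, migratory minus premigratory (horizontal axis), of each gene list (vertical axis, tested members in brackets), with the median of all genes, 2.67, as a solid line and 0 as a dotted line. Grey marks lists not called, red lists that rose more and blue lists that rose less than other genes (camera, correlation 0.01), none of which keeps its call with an estimated correlation.

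Some markers of muscle, a tissue the migratory crest passes, rose. Of 27 tested muscle and somite genes 6 rose (11 when adjusted over the list alone), with a median of 5.01 (camera, adjusted p = 0.0317, but adjusted p = 0.754 with an estimated correlation, and 0.0631 to 0.180 without any of 8 single libraries). The muscle creatine kinase ckma was at 1.71 ± 1.68 (SD, n = 4) and 13400 ± 16278 (SD, n = 8), and the muscle actin actc1b at 36.1 ± 31.5 and 149360 ± 185450. The mean log2 value of the muscle list was 2.26 ± 0.54 in premigratory and 5.95 ± 2.26 in migratory libraries (exact permutation p = 0.0121, adjusted p = 0.0909 over 15 measures). Epidermis genes had a median of -1.36 with krt18b up among 28 (camera, adjusted p = 3.45e-09, but adjusted p = 0.466 with an estimated correlation). The mean log2 value of this list per library was 7.63 ± 5.15 and 6.99 ± 3.67 (exact permutation p = 0.812), from 3.14 to 13.67 among premigratory libraries. That of neural tube markers was 1.604 ± 0.35 and 2.68 ± 0.66 (exact permutation p = 0.0202, adjusted p = 0.101 over 15 measures). The 3 endothelium genes tested (median -2.24, camera, adjusted p = 0.0243, but adjusted p = 0.466 with an estimated correlation) and the 8 otic and placode genes (median -0.98, camera, adjusted p = 0.00284, but adjusted p = 0.466 with an estimated correlation) also lay below other genes. The endothelium median is that of SOX7, at 47616 in premigratory replicate 1 and 6.37 or less in the other premigratory libraries. Over all genes of the endothelium list the mean log2 value was 1.25 ± 0.45 in premigratory and 1.35 ± 0.52 in migratory libraries (exact permutation p = 0.764). For the otic list it was 2.52 ± 0.68 and 2.62 ± 1.34 (exact permutation p = 0.883). Among the random lists matched on mean value, the medians of epidermis, endothelium and otic genes lay at percentile 0, 0.13 and 0.03. These random lists also draw genes separately, while epidermis genes varied together (estimated correlation 0.64). With quantile normalisation the calls of the muscle, endothelium and otic lists were lost (adjusted p = 0.0781, 0.0578 and 0.0975). The lists of neural tube (adjusted p = 0.0787), blood (adjusted p = 0.704, and 0.0485 with the replicate block), notochord (adjusted p = 0.201) and yolk and germ line genes (adjusted p = 0.204) did not pass, although FABP7, UROD and gra rose. Without premigratory replicate 1, the richest in keratin, and migratory replicate 5, the richest in globin, 1237 genes were higher and 18 lower, a comparison chosen after the data were seen.

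**Figure D4:**
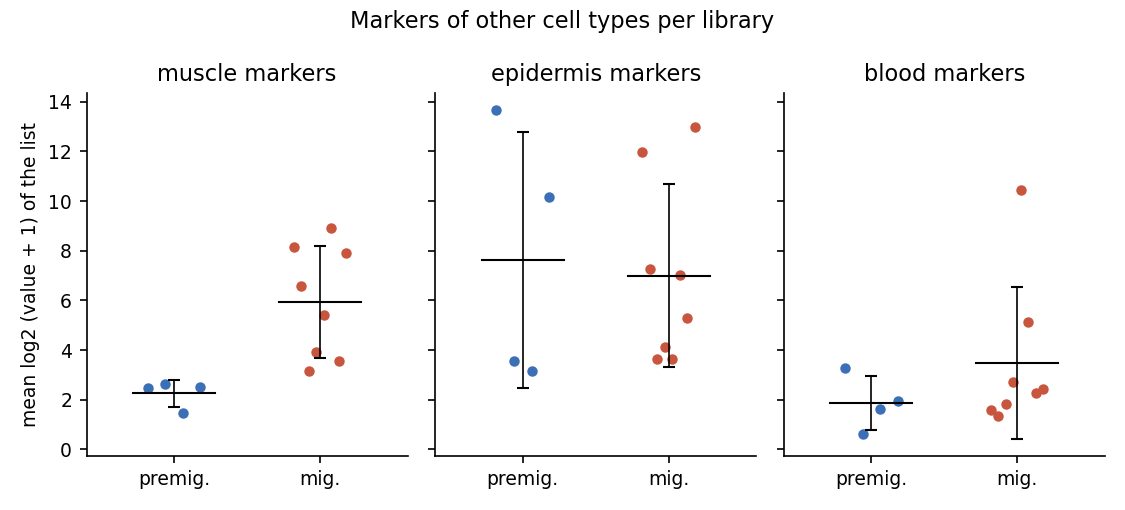
Mean log2 of the value plus 1 (vertical axis) over the lists of muscle, epidermis and blood markers in premigratory (blue) and migratory (red) libraries, with 1 point per library, the mean as a horizontal line and the SD as an error bar. The muscle list is at 1.46 to 2.62 in premigratory and 3.17 to 8.91 in migratory libraries.

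Premigratory libraries also differed more among themselves. The median SD of a gene on the log2 scale was 3.31 in premigratory and 2.93 in migratory libraries, and 60.8% of tested genes had the larger SD in premigratory libraries. Over tested genes the mean Pearson correlation of libraries was 0.377 within premigratory pairs, 0.447 within migratory pairs and 0.337 between the groups. The mean distance of a library to its group's centre was 3.76 ± 0.35 (SD, n = 4) in premigratory and 3.00 ± 0.44 (SD, n = 8) in migratory libraries (exact permutation test, two-sided, p = 0.0162). The difference no longer passed without premigratory replicate 1 or over genes with a mean of 50 or more.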

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

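Results are listed here because 1 library lay far from the others of its group, by the ratio of its gap to the nearest library to the range of the group (Dixon's 95% critical value). Of 231 groups of values checked, 57 held such a library, where chance gives about 1 in 20, but the rule assumes values of 1 shape and many of these lie near 0. Over all 172 genes of the naming rule, whether or not the text names them, 89 of 373 did.

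Migratory replicate 5 had 32.1% of its total in the 10 most abundant genes (ratio 0.654) and 45.8% in the 100 most abundant (ratio 0.67), and a mean log2 value of blood markers of 10.45 (ratio 0.584). Migratory replicate 4 had 13.4% ribosomal protein genes (ratio 0.69) and endothelium markers at 2.44 (ratio 0.536). Muscle markers were lowest in premigratory replicate 3, at 1.46 (ratio 0.857), and otic markers in premigratory replicate 2, at 1.501 (ratio 0.887).

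In premigratory replicate 1 the log2 value, with the ratio in brackets, was 0.00 for rnaset2 (0.839), 15.57 for si:dkeyp-4c4.1 (0.872), 1.00 for twist1b (0.933), 11.40 for TXNRD3 (0.852) and 2.80 for crestin (0.864). In premigratory replicate 2 the log2 value, with the ratio in brackets, was 1.54 for WNT11 (1), 1.12 for emc9 (1), 10.35 for TDP2 (0.85), 0.97 for HUS1 (1), 11.52 for EI24 (0.908), 10.73 for ARPC5 (0.998) and 0.98 for MITF (1). In premigratory replicate 3 the log2 value, with the ratio in brackets, was 1.94 for RRM2B (1). In premigratory replicate 4 the log2 value, with the ratio in brackets, was 2.29 for UFC1 (1), 2.71 for si:ch211-210c8.7 (1), 1.59 for rad9a (1), 0.68 for mdm2 (1), 9.84 for DDB2 (0.837), 0.00 for ERCC2 (0.975), 2.35 for PRIM1 (1), 7.41 for CDC45 (1), 2.58 for bub1ba (1), 0.00 for SUN1 (0.972), 2.29 for BMI1 (0.873), 3.14 for PAX3 (1), 0.00 for DLX5 (0.839), 1.48 for erbb3b (1), 8.91 for cdkn1a (1), 10.04 for LMNB2 (0.911) and 11.09 for CHEK1 (0.911).

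In migratory replicate 1 the log2 value, with the ratio in brackets, was 0.00 for PRIM1 (0.78), 0.00 for CDC45 (0.736), 1.58 for BACE2 (0.661), 2.56 for HOXD10 (0.543), 0.00 for LBR (0.819) and 0.00 for XRCC6 (0.758). In migratory replicate 2 the log2 value, with the ratio in brackets, was 1.11 for RRM2B (0.768). In migratory replicate 4 the log2 value, with the ratio in brackets, was 2.59 for ERCC2 (0.732), 3.43 for CHMP7 (0.684), 6.56 for RNF2 (0.783) and 2.77 for YAP1 (0.727). In migratory replicate 5 the log2 value, with the ratio in brackets, was 0.00 for tsg101a (0.753), 0.00 for FABP7 (0.576), 8.66 for GAPDHS (0.64) and 16.06 for UROD (0.779). In migratory replicate 6 the log2 value, with the ratio in brackets, was 7.63 for twist1b (0.741). In migratory replicate 7 the log2 value, with the ratio in brackets, was 4.91 for GAPDH (0.567), 3.80 for WNT11 (0.572) and 4.29 for MITF (1). In migratory replicate 8 the log2 value, with the ratio in brackets, was 9.17 for DLX5 (0.747).

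Of MITF 1 of 2 identifiers, the 1 that was not tested, is meant here. No explanation of single libraries was tested.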

How the results depend on the processing

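Alternatives named here as added were chosen after seeing the data. Of the 169 named genes tested, over 39 settings, 85 were called. The counts of 1508 higher and 16 lower genes became 986 higher with a pseudocount of 5, 821 with 10, 851 and 7 with no filter, and 936 higher with 8 libraries at 10 or more. Library weights left 5 lower genes, median of ratios gave 777 and 59, and quantile normalisation 139 and 53. The exact rank-sum test called 0 and 0, with 2449 higher and 130 lower genes at an unadjusted p under 0.05, and the fixed replicate block 0 and 0, with 2241 and 81, against 1543 and 17 with the number as a random block. The rank-sum p has a floor with 4 against 8 libraries. The 586 and 17 genes with separated groups were too few to pass the adjustment at that floor. Migratory numbers 1 to 4 gave 351 and 7, numbers 5 to 8 left 2 lower genes, an adjusted p under 0.01 left 370 and 0, and genes above 0 as a covariate 725 and 2. Leaving out each replicate gave 771 to 1911 higher and 6 to 19 lower genes. The higher count fell to 771 without premigratory replicate 3. The lower count was 8 and 6 without premigratory replicates 2 and 3, and 10, 9, 8 and 7 without migratory replicates 2, 3, 7 and 8.

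Of the added settings, genes at 10 or more as a covariate, which separates the groups completely, called 0 and 0, with 411 and 412 at an unadjusted p under 0.05. Genes at 10 or more in every library gave 9 and 2, and with TMM factors 7 and 11, so that lower genes outnumbered higher ones, with fewer genes tested in both. Without the premigratory libraries of highest DLX2 843 were higher and 11 lower, none of the 11 among the 16 above. With fewer libraries the log2 fold changes of the 9 of them that are named and were tested were -1.94 to -7.60 (adjusted p = 0.0744 to 0.203, limma), with ZBTB16 at -4.72 against -6.00 before. Tested against the median of all genes, 220 were higher and 633 lower.

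The 7 lists that rose more and 8 that rose less became 0 and 0 with an estimated correlation and 19 and 0 with fry, which tests against no change. Lists rising less numbered 1 with quantile normalisation and 5 on ranks. Leaving out each replicate gave 3 to 7 rising more, lowest without premigratory replicate 2, and 5 to 9 rising less, lowest without premigratory replicate 3. The Hox, glycolysis, pigment, ribosomal, epidermis and otic lists were called without each of the 12 libraries, and the endothelium list in the 8 of these settings that left it 3 tested genes, whereas the other 8 lost their calls without at least 1 library. Calls of lists rising less were gained without premigratory replicate 1 for early crest (0.0379), shared crest (0.0170) and mitochondrial genes (0.0105), without premigratory replicate 4 or migratory replicate 1 or 4 for neural tube (0.0317, 0.0434 and 0.0398), and without migratory replicate 5 or 6 for notochord genes (0.0245 and 0.0300). Added settings gave 2 and 2 (genes at 10 or more as a covariate), 1 and 0 (genes at 10 or more in every library), 3 rising less without the keratin-rich and globin-rich libraries, and 3 and 5 without the libraries of highest DLX2. Signs turned, with these adjusted p, for replication (0.950) and immediate early genes (0.976) under quantile normalisation. Under fry the sign is against no change and not against other genes, so its upward sign for replication (0.209), mitosis (0.264), immediate early (0.212), heat shock (0.295) and ribosomal genes (0.952) is no turn of the means, which were above 0 in the main test. Signs turned with genes at 10 or more as a covariate for replication (0.413), mitosis (0.961), ribosomal (1.12e-08) and endothelium genes (0.966). With that covariate the log2 fold changes of CBX8, ctnna1 and ARPC5 became -2.21, -0.070 and -2.68, and that of ARPC3 against the median of all genes -0.77, where the median is subtracted from every gene alike.

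The difference in genes detected was 5070 at a value of 10 or more, and that in genes above 0, 3712, became 2075 to 5999.8 with each replicate left out. The difference in distance to the centre, -0.76, was -0.57 over genes with a mean of 50 or more and -0.64 to -1.03 with each replicate left out, losing its call without premigratory replicate 1. The block changed no call of a list besides those given with it. Count models on whole reads were not run, since whole reads were not recovered. The cause of these changes was not tested. Depth limits the rest, since a value under 10 in a library of 20 cells does not show that a transcript was absent.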

Other observations

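The tests in this part were chosen after the result was seen, except the count of other splits and the head crest list, whose predictions were written before they were tested. DLX2, a transcription factor best known from crest of the head and from the forebrain, was at 27150, 20450 and 10750 in premigratory replicates 2, 3 and 4 and at 9.33 or less in the other 9 libraries (exact permutation p = 0.00404, for a gene picked by its values). Its second identifier was at 2.94 or less in all libraries. DLX5 and twist1b, which fell in the main test, were not high in every premigratory library, with DLX5 at 0 in replicate 4 and twist1b at 1.00 in replicate 1. Without premigratory replicates 2 and 3, the richest in DLX2, 11 genes were lower, none of them among the 16 called with all libraries, in a comparison with only 2 premigratory libraries left. The log2 fold changes of those of the 16 that are named and were still tested stayed below 0. For the 8 genes with separated groups this sign was fixed, since every premigratory library lay above every migratory library. SERPINH1 was also above every migratory library in both premigratory libraries left. DLX5 and twist1b fell under the filter there. DDX51, SERPINH1 and olfcr1 were at -7.60, -7.22 and -5.19, against -8.07, -6.74 and -4.88 with all libraries. ZBTB16, pprc1 and si:ch211-212k18.5, which were highest in replicates 2 and 3, went from -6.00, -6.19 and -7.52 to -4.72, -5.19 and -6.38. Neither the lost calls nor the kept signs tell how far the lower genes rest on these 2 libraries.

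The share of Hox values at 10 or more was higher in migratory libraries in every paralog group but group 2. It went from 15.0% to 92.5% in group 9, from 31.2% to 87.5% in group 3 and from 4.17% to 33.3% in group 13, and for the 2 genes of group 2 it was 75% in premigratory and 43.8% in migratory libraries. These shares were not tested by group and follow no plain order along the cluster.

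The first pattern is the many higher and few lower genes. Of 100 splits of the libraries into 4 and 8, only the real one reached its 1524 calls, with 601 as the highest of the others, which argues against a difference by chance; only 2 other drawn splits parted all 4 numbered pairs, with at most 6 calls. A hypothesis is that fewer transcripts were captured in premigratory libraries, in line with a median log2 fold change of 0.86 in the 10% of genes with the highest mean, where 152 genes were still higher and 7 lower. The deposited values were also thinned to 1 total. Every migratory library then kept at least 7591 genes at 10 or more and every premigratory library at most 6806 (a gap of 785). With this thinning 982 genes were higher and 20 lower, so unequal sums of the deposited values alone did not give the difference. Lower depth of reads stays open, since the values are normalised and their sums need not follow the reads.

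The second pattern is muscle transcripts in migratory libraries. The 27 muscle genes varied together over the 8 migratory libraries, with a median pairwise Spearman correlation of 0.548 against 0.0476 in 2000 matched random lists (percentile 100). RNA of muscle cells in some of these libraries would give this. So would any genes regulated together, so the test cannot tell the source of the RNA. In camera the estimated correlation over all 12 libraries was 0.41 for muscle genes and 0.40 for pigment genes. Cells were sorted for a crest reporter, and how RNA of muscle cells would pass the sort was not tested. A lower share of crest cells in general would raise markers of other cell types alike. Muscle minus the mean of the 7 other lists went from -0.32 ± 0.98 (SD, n = 4) to 2.86 ± 1.62 (SD, n = 8, exact permutation p = 0.00404). Against single lists the exact permutation p was 0.00202 (otic) to 0.305 (blood), with 0.0566 for epidermis, which was tested first. These tests cannot decide the question, since several of these lists lie near 0 and epidermis was at 13.67 and 10.16 in premigratory replicates 1 and 4. Muscle, epidermis and otic markers were higher together in migratory replicates 1, 2, 6 and 8 (6.56 to 8.91, 7.01 to 12.99 and 3.075 to 4.55). In migratory replicates 3, 4, 5 and 7 they were lower (3.17 to 5.425, 3.64 to 5.305 and 0.79 to 2). The remaining lists did not part these libraries.

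The third pattern is the low Hox genes of premigratory libraries, with migratory replicate 5 inside their range. Of premigratory Hox values 13.3% were at 10 or more, against 46.1% in 10000 random lists matched on the migratory mean (percentile 0). This cannot weigh against loss of transcripts, since the Hox list was picked for its rise in these same values. The random lists also draw genes separately, while the tested Hox genes varied together (estimated correlation 0.31). A hypothesis was that cells of the head crest were among the premigratory cells, with 22 head crest genes predicted to be higher there, 5 of which were also in lists tested before; this was not met, since their mean log2 value was 2.40 ± 1.07 (SD, n = 4) in premigratory and 2.76 ± 0.59 (SD, n = 8) in migratory libraries (exact permutation p = 0.453). The question stays open, since genes in general were higher in migratory libraries by a median of 2.67, which works against the prediction. Many of the 22 genes were also near 0 in most libraries, so the list could show little either way. Premigratory replicate 2 had the highest mean of all libraries, 3.87, close to 3.84 in migratory replicate 6. Premigratory replicates 1 and 4 had the lowest means of all libraries. The 22 genes left out head crest genes already seen in these libraries, namely DLX2, DLX5, twist1a, twist1b and PDGFRA. The mean log2 value of those seen genes was 4.12 to 10.92 in premigratory and 0.31 to 4.76 in migratory libraries. Since these values were known beforehand, they are no test of the hypothesis. Stage differs between the groups, and the axial level of the premigratory cells is not given in the sources used here.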
